A study of Danio rerio with 48 samples.

How the data were processed

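Bulk RNA-seq was measured in 48 libraries from zebrafish (Danio rerio, strain AB) of a preclinical model of inflammatory bowel disease. Per the labels, the libraries came from lymphoid or myeloid cells of naive fish or of fish given TNBS (trinitrobenzene sulfonic acid, a hapten used to inflame the intestine). Each of these sets was split into a control, 20 µM propyzamide and a lower dose of this herbicide, which gave 12 groups with 4 libraries each. The titles and the series design give the lower dose as 1 µM and the sample descriptions as 4 µM, and it is called 1 µM here. Libraries were prepared with SMART-seq2, a full-length cDNA method made for very small amounts of RNA, per the labels' protocols. How the cells were isolated, whether each library came from separate fish, and the age and sex of the fish are not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

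Each deposited table holds, per the file headers, an estimated count, a TPM value (transcript abundance scaled to a fixed sum per library), a length and an effective length for each of 59290 zebrafish transcripts. Per the submitters' processing notes, the authors made these estimated counts and TPM values with kallisto, which assigns reads to transcripts without aligning them to a genome. The version of kallisto, its index and the annotation release are not given in the sources used here. Such estimated counts are expected values that need not be whole, because reads that fit several isoforms or near-identical gene copies are divided among them. The value of a single transcript is therefore uncertain where it has such relatives. The estimated counts were rounded to whole numbers for the tests, and shares of counts were computed from the unrounded estimates. The deposited effective lengths served in 1 alternative, and the TPM values entered no test.

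The identifiers are Ensembl transcript IDs. None of the 59290 matched the gene name table used here and none matched the RefSeq gene table, and the deposited tables do not pair them with names. Tests were therefore made per transcript, although tests per gene had been planned, and no gene is named. The 30 gene lists fixed before the data were examined, with their marker lists of other cell types, and the gene names fixed with them could not be looked up, so no list was tested. At most 2 transcripts that rose and 2 that fell are printed for a comparison.

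Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by the trimmed mean of M values (TMM), and quasi-likelihood tests were made with glmQLFit and glmQLFTest. Propyzamide and TNBS comparisons were fitted on the 24 libraries of a cell class, and comparisons across cell classes on all 48 libraries. All groups of a fit shared 1 estimate of the spread. The filter kept 249 transcripts in the fit of all libraries, 203 in the lymphoid fit and 116 in the myeloid fit. In the fit of all libraries these held between 40.2% and 76.7% of a library's counts. Adjusted p-values are Benjamini-Hochberg values over the transcripts tested, and a transcript was called at an adjusted p under 0.05. Standard errors were derived from the fold change and its F statistic. A fitted fold change of a transcript absent from a group depends on edgeR's prior count of 0.125. For such transcripts the text gives a lower bound from pooled counts, with 3 counts over the group as the floor.

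The rule for printed transcripts, fixed before the data were examined, took called transcripts with a mean log2 CPM of at least 2 whose direction held in every library of a pair of groups, or in every matched pair of groups for an average, ordered by fold change. For a difference between effects no such condition applied. Transcripts printed outside this rule are marked as chosen after their values were seen. Per-library measures were compared by exact two-sided permutation tests over all reassignments of the compared libraries. Detected transcripts were compared after thinning each library to 1000 counts. Two-sided tests were used unless stated. Intervals of shares are 95% exact binomial (Clopper-Pearson) intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

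A share of counts in transcripts higher in myeloid libraries was computed for each library as a measure of cell class. The transcripts were called between the cell classes in the other 5 matched treatments (with a log2 difference over 2 for the myeloid set), so that no library helped to choose its own set. The sets held 11 to 18 transcripts and differed between treatments, so shares were compared only within a treatment.

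The pipeline was tested on counts simulated from the real means, totals and dispersions, with 200 transcripts changed 2-, 4-, 8- or 16-fold in each of 20 simulations. Of the changed transcripts that passed the filter, 73.8% were recovered at 4-fold and 20.2% at 2-fold in the design of 20 µM against control in naive lymphoid libraries (median 251 transcripts tested). The same design in myeloid libraries recovered 44.5% at 4-fold and 8.8% at 2-fold (median 128.5 tested). For TNBS against naive controls, 4-fold changes were recovered in 67.4% of cases in lymphoid libraries (median 238.5 tested) and in 69.7% in myeloid libraries (median 122 tested). Between the cell classes 80.7% were recovered at 2-fold (median 321.5 tested). All these shares are of changed transcripts that passed the filter, and those that it removed are not counted. Many transcripts changed at once in these simulations, which eases the adjustment for multiple tests.

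Within groups, 60 of the 72 pairs of libraries had enough counts for a chi-square comparison. It gave 2.10 to 48.7 per degree of freedom, so no pair agreed within sampling noise. Each second index sequence held 1 cell class and state and each first index sequence 1 dose, so the position in the library pool cannot be separated from the groups.

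Alternatives set before the data were examined were DESeq2 1.42.0 in place of edgeR, size factors in place of TMM, no filter on low counts, an offset for effective length and fits of the compared groups alone. Others were libraries of low depth left out (under 0.25 of the median total or under 0.5 of the median number of transcripts), limma 3.58.1 voom with sample weights, the first index as a block, and each library left out in turn. Only ENSDART00000062587 had counts in all 48 libraries, so the planned size factors would have rested on 1 transcript there, and size factors over positive counts (poscounts in DESeq2) were used in their place. Added after the data were seen were TMM with singleton pairing, a fit without 2 libraries that stood apart, a comparison at equal depth, and TNBS against naive averaged over the 3 doses.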

Results

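The data collected were transcript abundances in lymphoid and myeloid cells of zebrafish, in a design that asks what the herbicide propyzamide does to immune cells with and without intestinal inflammation. Lymphoid cells (the lineage of T, B and natural killer cells) and myeloid cells (the lineage of neutrophils and macrophages) each gave 24 libraries. Of these, 12 were naive and 12 came from TNBS-treated fish, and each set of 12 held 4 controls, 4 libraries at 20 µM propyzamide and 4 at 1 µM. Sample descriptions in the labels name the lower dose as 4 µM. Transcripts are given by their Ensembl IDs, since no gene names could be attached.

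The libraries were shallow. Total estimated counts ranged from 46 to 71670 with a median of 8305, and between 26 and 8470 transcripts had at least 1 count. A library under 100 counts occurred in the naive control myeloid group (98 counts) and in the naive 1 µM myeloid group (46 counts). Depth was uneven across the TNBS comparison in myeloid cells, where the TNBS controls held 21733 to 34255 counts and the naive controls 98 to 24735 (exact permutation test on log10 totals, p = 0.0571, n = 4 each, adjusted p = 0.343 over 30 tests of library measures). One transcript, ENSDART00000062587, was the most abundant in 47 of the 48 libraries, with a median of 15.2% of counts and a range from 3.89% to 64.3%.

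**Figure D1:**
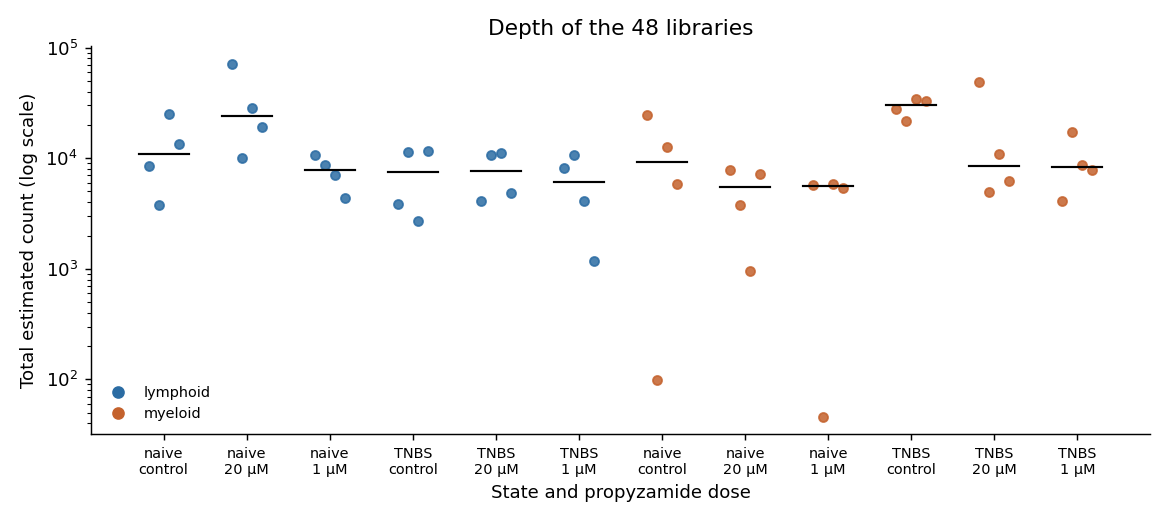
Total estimated count of each of the 48 libraries on a log axis, by state and propyzamide dose, with lymphoid libraries in blue and myeloid libraries in orange. Points are libraries and lines are group medians, and totals run from 46 to 71670.

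Lymphoid and myeloid libraries differed most clearly. In the average over the 6 matched treatments, 37 of 249 transcripts were called, of which 30 were higher in myeloid and 7 higher in lymphoid libraries. The 2 myeloid-high transcripts with the largest differences were close to absent from lymphoid libraries, whereas others of the 30 had counts in both classes. ENSDART00000194692 had 980 counts in myeloid libraries, in 17 of 24, and no count in any of the 24 lymphoid libraries, so that it was at least 315-fold higher against a floor of 3 counts over the pooled lymphoid libraries. ENSDART00000194405 took 0.219% ± 0.178 of counts in myeloid libraries (SD, n = 24) and 0.00298% ± 0.0102 in lymphoid libraries (SD, n = 24), a log2 difference of -6.83 (SE 0.50, edgeR adjusted p = 1.35e-16). Lymphoid-high transcripts differed less. ENSDART00000187593 was higher by 1.36 on the log2 scale (SE 0.45, edgeR adjusted p = 0.0280) and ENSDART00000192310 by 0.79 (SE 0.24, edgeR adjusted p = 0.0159), at 0.271% ± 0.112 against 0.129% ± 0.107 of counts (SD, n = 24 each). The log2 differences of all 37 ran from -7.75 to 1.38, the lower end being the fitted value of ENSDART00000194692, which depends on the prior count. Both lymphoid-high examples lost their call with no filter on low counts and with low-depth libraries left out, and also without any 1 of 15 and 11 of the 48 libraries, whereas both myeloid-high examples kept theirs in every such fit.

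The share of counts in myeloid-high transcripts, chosen for each treatment from the other 5, was higher in each myeloid than in each lymphoid library in 4 of the 6 treatments. The exceptions were naive controls and TNBS 1 µM, where 1 library each stood apart. Naive control lymphoid replicate 1, at 4.1% (95% interval 3.71% to 4.57%), lay above the myeloid libraries of its treatment (0.683% to 2.44%), and ENSDART00000117596 alone made up 3.84%. TNBS 1 µM myeloid replicate 3, at 0.175% (95% interval 0.0972% to 0.286%), lay within the range of the lymphoid libraries of its treatment (0.140% to 0.763%). Without both libraries 47 transcripts were called between the cell classes. In the 4 treatments with full separation the order rests on point values. Naive 1 µM myeloid replicate 2, at 2.15%, held 1 count in these transcripts (95% interval 0.0550% to 11.5%). In TNBS 20 µM the 95% intervals of the lowest myeloid (0.480% to 0.905%) and the highest lymphoid library (0.262% to 0.697%) overlapped.

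**Figure D2:**
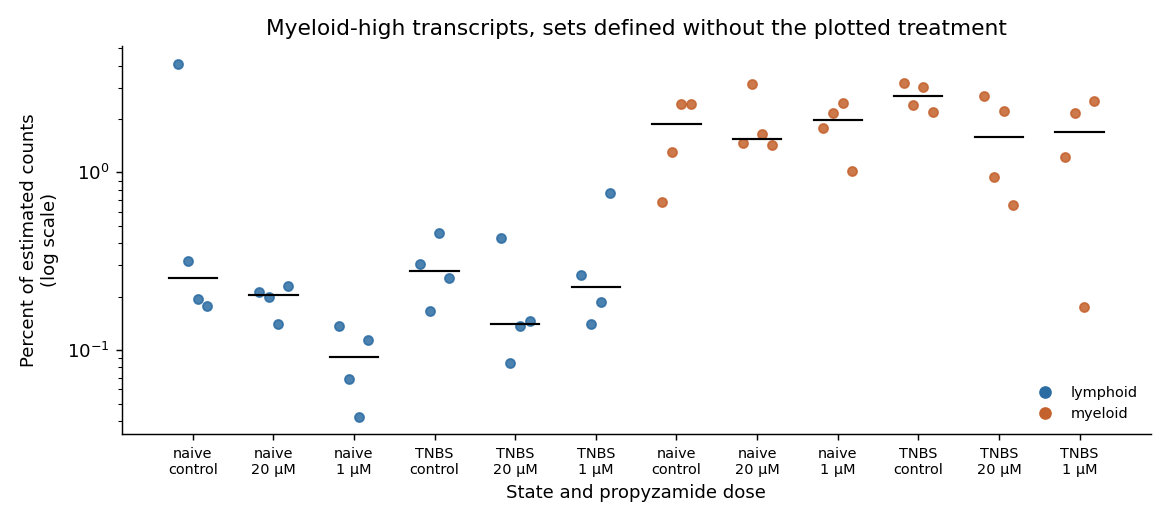
Percent of estimated counts in myeloid-high transcripts for each library, on a log axis, by state and dose, with lymphoid libraries in blue and myeloid libraries in orange. Points are libraries and lines are group medians. The sets of 11 to 18 transcripts were chosen without the plotted treatment and differ between treatments. Naive control lymphoid replicate 1 lies at 4.1% and TNBS 1 µM myeloid replicate 3 at 0.175%.

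TNBS against naive, without propyzamide, asks what the inflammation model alone changed. In myeloid libraries 6 of 116 transcripts were called and all 6 were higher in TNBS. ENSDART00000105036 had no counts in the 4 naive control libraries and 32 to 111 counts in each TNBS control library, 0.259% ± 0.0821 of counts (SD, n = 4). It was at least 38.61-fold higher against a floor of 3 counts over the pooled naive controls (edgeR adjusted p = 3.68e-04), and at least 16.5-fold higher without naive control replicate 1, which held most of the pooled naive counts. ENSDART00000159326 was likewise absent from the naive controls and took 0.165% ± 0.0593 of counts in TNBS (SD, n = 4), at least 23.1-fold higher by the same floor (edgeR adjusted p = 0.00466) and at least 9.88-fold without that replicate. Across propyzamide doses as well, ENSDART00000159326 had counts in 11 of 12 TNBS and in 0 of 12 naive myeloid libraries, and ENSDART00000105036 in 11 of 12 and in 5 of 12. The naive myeloid libraries with totals of 46, 98 and 951 counts are too shallow for a zero to say much. The other 4 called transcripts were higher by 2.45 to 3.69 on the log2 scale. In a set of 5 transcripts higher in myeloid than lymphoid cells, chosen from naive propyzamide-treated libraries alone and holding 1 of the 6, the pooled share was 4.00% ± 0.684 of counts in TNBS controls and 1.69% ± 0.663 in naive controls (SD, n = 4 each; exact permutation test p = 0.0286, the smallest possible, adjusted p = 0.114 over 4 tests). The 4 lymphoid-high transcripts of that choice took 0.404% ± 0.0691 and 0.373% ± 0.308 (SD, n = 4 each; exact permutation test p = 0.8286). A pooled share follows its most abundant members, and the median log2 change of the 5 myeloid-high transcripts was 0.148. ENSDART00000117596, itself called higher in myeloid libraries, took 2.25% to 3.63% in TNBS and 0 to 0.762% in naive myeloid controls. A single abundant transcript could thus carry such a rise, which need not be a shift of the set.

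DESeq2 called 5 transcripts in this comparison and voom with sample weights 2, and the voom fit no longer called ENSDART00000159326. The count was 2 without naive control replicate 1, 3 without TNBS control replicate 1, 3 without TNBS control replicate 3 and 18 in a fit of the compared groups alone. It was 3 with low-depth libraries left out, with the index block and with no filter on low counts. Averaged over the 3 doses, a comparison added after the data were seen, 7 transcripts were higher in TNBS and 0 lower, of which 4 were also called in the controls alone. DESeq2 and voom each called 8 there. That count was 2 without TNBS 1 µM replicate 2, 3 without TNBS control replicate 1, 13 without naive 1 µM replicate 3, 11 without naive 1 µM replicate 4 and 11 without TNBS 1 µM replicate 3.

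**Figure D3:**
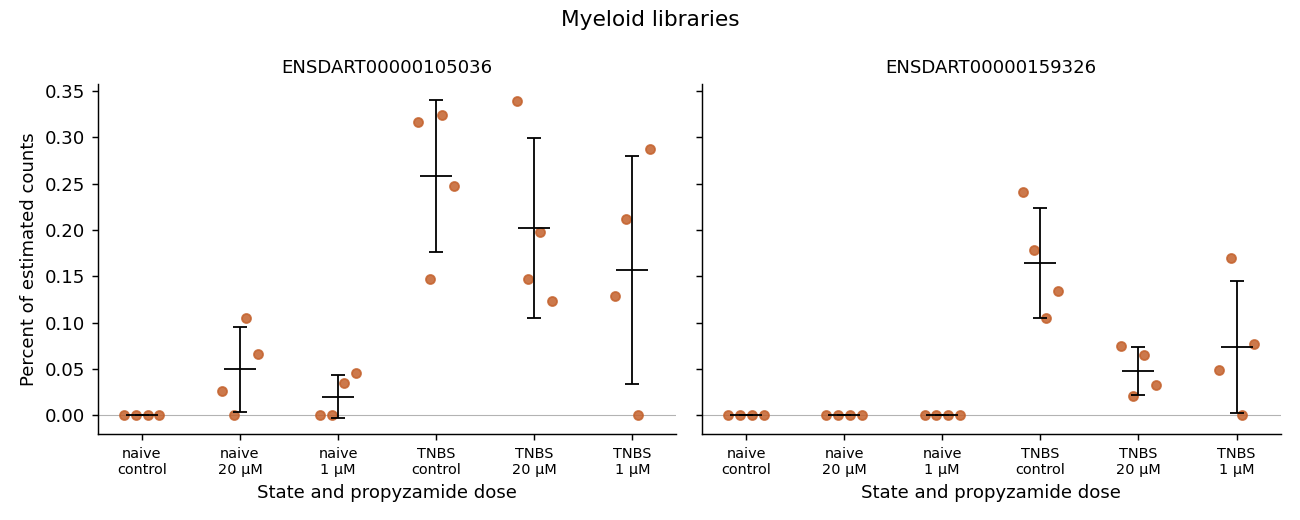
Percent of estimated counts in ENSDART00000105036 and ENSDART00000159326 in the 24 myeloid libraries, by state and propyzamide dose. Points are libraries and black marks are the mean and SD of 4 libraries. ENSDART00000159326 has counts in 11 of 12 TNBS libraries and in 0 of 12 naive libraries, which include shallow ones with totals of 46, 98 and 951 counts.

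In lymphoid libraries TNBS against naive controls gave 0 calls among 203 transcripts with edgeR, DESeq2 and voom, and 10 transcripts at an unadjusted p under 0.05, where 10.2 would be expected by chance. The smallest edgeR adjusted p was 0.124. The count was 2 without any 1 of naive control replicates 2, 3 and 4. In the fit of all libraries of the class, the smallest p-values belonged to ENSDART00000126982 and ENSDART00000117596, chosen after their values were seen. They took 1.76% and 3.84% of counts in naive control replicate 1, far above the other naive controls. Leaving out another naive control gives that library more weight. The median 95% range reached 2.66-fold to either side of a fold change. In simulations 13.9% of 2-fold and 67.4% of 4-fold changes were recovered among the changed transcripts that passed the filter. Changed transcripts that the filter removed are not counted in these shares. The average over the 3 doses also gave 0 calls with all 3 tools and 9 transcripts at an unadjusted p under 0.05, and it gave 1 call without TNBS 1 µM replicate 1.

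The difference of the TNBS effect between the cell classes was called for 2 of 249 transcripts. ENSDART00000117596 had a difference of -5.38 on the log2 scale (SE 1.27, edgeR adjusted p = 0.0190), with lymphoid below myeloid, and ENSDART00000126982 one of -3.91 (SE 0.98, edgeR adjusted p = 0.0216). Both rested on naive control lymphoid replicate 1. Without it 0 transcripts were called and the differences were -0.40 and -0.38. The count was also 0 without naive control myeloid replicate 2, 1 without naive control myeloid replicate 3, 5 without naive control lymphoid replicate 2 and 4 without TNBS control lymphoid replicate 1.

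Propyzamide against control asks what the herbicide itself changed. In naive lymphoid libraries, 2 of 203 transcripts were called lower at 20 µM and 1 at 1 µM, and 0 were called higher. They fall outside the rule for printed transcripts, because the groups overlapped, and were chosen after their values were seen. ENSDART00000126982 differed by -3.30 on the log2 scale at 20 µM (SE 0.79, edgeR adjusted p = 0.0293) and by -3.61 at 1 µM (SE 0.85, edgeR adjusted p = 0.0274). ENSDART00000117596 differed by -4.00 at 20 µM (SE 1.00, edgeR adjusted p = 0.0293) and by -3.80 at 1 µM (SE 1.02, edgeR adjusted p = 0.0627). A single control library set these values. In naive control replicate 1, ENSDART00000117596 took 3.84% of counts and ENSDART00000126982 took 1.76%, against 0.0843% to 0.106% and 0.0513% to 0.288% in the other 3 controls. Without replicate 1, both dose comparisons had 0 calls, and ENSDART00000126982 stood at 0.35 at 20 µM and 0.01 at 1 µM. DESeq2 called 0 transcripts at either dose. Voom called 2 others at 20 µM, both higher, and 0 at 1 µM, and it gave ENSDART00000126982 a value of 0.57 and of 0.38.

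The counts in naive lymphoid libraries moved with other single libraries as well. At 20 µM they were 4 without control replicate 2, 5 without control replicate 3, 5 without control replicate 4, 1 without 20 µM replicate 1 and 0 without any 1 of 20 µM replicates 2, 3 and 4. At 1 µM they were 2 without any 1 of control replicates 2, 3 and 4 or 1 µM replicate 1, and 0 without any 1 of 1 µM replicates 2, 3 and 4.

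In TNBS lymphoid libraries no transcript passed the test at either dose. There were 0 calls among 203 transcripts at 20 µM and at 1 µM with edgeR, DESeq2 and voom, with 4 and 8 transcripts at an unadjusted p under 0.05 and 10.2 expected by chance. The median 95% range reached 2.65-fold at 20 µM and 2.76-fold at 1 µM. Libraries of the 1 µM group held fewer transcripts per 1000 counts than their controls, 493 ± 81.6 against 585 ± 25.1 (SD, n = 4 each; exact permutation test p = 0.0286, adjusted p = 0.286 over 30 tests). Their 50 most abundant transcripts took 45.0% ± 8.78 against 33.1% ± 3.29 of counts (SD, n = 4 each; exact permutation test p = 0.0286, adjusted p = 0.286). In each case this is the smallest p that the exact test of 4 against 4 libraries can give, and neither difference passed the adjustment.

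In myeloid libraries propyzamide against control gave 0 calls among 116 transcripts in each of the 4 comparisons with edgeR. At an unadjusted p under 0.05 there were 9 transcripts at 20 µM and 11 at 1 µM in naive libraries, and 1 and 14 in TNBS libraries, with 5.8 expected by chance. DESeq2 called 3 transcripts at 1 µM in naive libraries, 1 higher and 2 lower, and 0 in the other 3 comparisons, and voom called 0 in all 4. With edgeR there was 1 call at 1 µM in naive libraries without control replicate 4. The median 95% range was widest at 1 µM in naive libraries, at 3.2-fold, where a library held 46 counts, and it was 2.54-fold at 20 µM in TNBS libraries.

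The 2 doses were compared with each other in the 4 sets, and edgeR called 0 transcripts in each. In naive myeloid libraries 19 transcripts had an unadjusted p under 0.05, the smallest adjusted p was 0.0686, DESeq2 called 3 transcripts, all higher at 20 µM, and voom called 0. With edgeR there were 2 calls without 20 µM replicate 2, 1 without 20 µM replicate 3 and 1 without 1 µM replicate 4. In the other 3 sets, 1 transcript in naive lymphoid, 7 in TNBS lymphoid and 1 in TNBS myeloid libraries had an unadjusted p under 0.05, and DESeq2 and voom called 0.

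Averaged over naive and TNBS, 20 µM propyzamide gave 0 calls in either cell class with edgeR, with 6 transcripts at an unadjusted p under 0.05 in each. The median 95% range was 1.95-fold in lymphoid and 2.05-fold in myeloid libraries. DESeq2 called 0 in lymphoid and 1 in myeloid libraries, and voom 0 in both. The interaction of 20 µM with TNBS, which asks whether the herbicide acted differently under inflammation, gave 0 calls in lymphoid libraries, with 5 transcripts at an unadjusted p under 0.05, 0 DESeq2 calls and 1 voom call. There was 1 call without naive control replicate 3 and 1 without naive control replicate 4.

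In myeloid libraries the interaction was called for 1 transcript of 116. ENSDART00000037346 had a difference of -4.76 on the log2 scale (SE 1.24, edgeR adjusted p = 0.0449). Its share ran from 0 to 0.0678% of counts in naive controls, from 0.0419% to 0.968% in naive 20 µM, from 0.186% to 0.427% in TNBS controls and from 0.0161% to 0.222% in TNBS 20 µM libraries (n = 4 each). Neither of its separate effects passed the test, at 3.27 in naive libraries (SE 1.00, edgeR adjusted p = 0.123) and -1.48 in TNBS libraries (SE 0.73, edgeR adjusted p = 0.929). The call was lost without any 1 of 10 of the 16 libraries, namely naive control replicates 1, 2 and 3, naive 20 µM replicates 2 and 3, TNBS control replicates 1, 2 and 3, and TNBS 20 µM replicates 2 and 4. It was also lost with DESeq2, voom, no filter, TMM with singleton pairing, low-depth libraries left out and the index block, with values from -5.82 to -3.42 over all fits run.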

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

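Several tests in this part were chosen only after the results were seen. They are those of equal depth, of splits of the libraries, of the fit without the odd control library and of myeloid RNA in that library. Those of the share of myeloid RNA and of the myeloid library with few counts in myeloid-high transcripts were chosen then too. In 130 sets of 4 libraries tested for a library far from the other 3, 14 had one. Chance gives about 1 in 20 for normally distributed values. That rate does not hold for skewed values such as totals, or for shares with zeros, where 1 count against 3 libraries at 0 is enough. Of the 130 sets, 61 were shares of transcripts picked for their calls in these same libraries. The 14 can therefore not be set against a chance rate.

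TNBS myeloid controls exceeded naive controls in 6 transcripts. Of the 35 splits of the 8 libraries only the real one, 1 of 35, gave as many, the highest other giving 0. That is the smallest share these splits can give, and it was not adjusted for the other comparisons split. The splits also ignored the first index sequences, which pair the replicates of both groups, and the fit with the index block called 3. Chance is therefore not excluded. For equal depth, 7 of the 8 libraries (3 naive, the shallowest left out) were thinned to 5000 counts and fitted alone. Of the 6, 4 could be tested and all 4 were called again, among 11 calls of 36 tested. A fit of the compared groups alone also gave more calls at full depth, so the thinned fit does not isolate depth. With the summed counts of the tested transcripts as the only scaling, in place of TMM, all 6 were called. The latter argues against the scaling factors as the whole cause. A part of depth stays open, as 3 were called with low-depth libraries left out. Whether a smaller share of myeloid RNA in the naive controls was the cause could not be decided. The 5 myeloid-high transcripts chosen without TNBS libraries had a median log2 change of 0.15 (0.148, scaled median absolute deviation 0.793). The least changed of the 6 would need 2.45, which argues against an even rise of all myeloid-high transcripts. However, these 5 are few and were chosen in shallow libraries. Most of the 6, though not ENSDART00000105036 and ENSDART00000159326, were themselves called higher in myeloid than in lymphoid libraries. That comparison included the same TNBS myeloid libraries, so it is not independent of the 6 calls. For ENSDART00000004812, 29 of 633 myeloid counts lay in naive libraries. The pooled share of the 5 was higher in TNBS controls, but it follows the most abundant transcripts and does not measure a shift of all 5. The log2 changes of the 5 ran from -0.39 to 2.45, with a median of 0.10 over the 4 not called. A contribution of myeloid share therefore stays open, as do a response of myeloid cells to TNBS, which was not tested, and the index sequences, which follow cell class and state and cannot be told apart from it.

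The transcripts lower under propyzamide in naive lymphoid libraries, and the 2 that differed in their TNBS effect between cell classes, may reflect 1 control library unlike the rest. Naive control lymphoid replicate 1 lay far from the other 3 controls, with 64.9% of counts in its top 50 transcripts (others 25.9% to 30.5%), 4.1% in myeloid-high transcripts (others 0.176% to 0.316%) and 0.322% in lymphoid-high transcripts (others 1.63% to 1.72%). It also stood apart in ENSDART00000117596, at 3.84% and thus most of that myeloid-high share, and in ENSDART00000126982, at 1.76%, and without it the comparisons of 20 µM and 1 µM with control had 0 calls. Myeloid RNA in it, if made up as in the 21 myeloid libraries compared, is argued against. The other 17 myeloid-high transcripts had 22 counts (upper 95% bound 33.31), with 15 of them at 0. That is 28.1% of the 78.3 counts (lower 95% bound 51.8) that ENSDART00000117596 would bring at the lowest ratio in those 21 libraries. These bounds cover counting error only, and myeloid RNA of another make-up was not tested. What else sets this library apart stays open, with no biological explanation tested.

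TNBS 1 µM myeloid replicate 3 held few counts in myeloid-high transcripts, 0.175% against 1.23% to 2.54% in the other 3 libraries of its group. Low depth is argued against, as the upper 95% bound was 0.286%. An exchange of labels with a lymphoid library of the same treatment is argued against too, since 0 of the 4 lymphoid libraries reached the range of those 3. Lymphoid RNA in this library remains a possible explanation: its lymphoid-high transcripts took 1.82% of counts, against 1.02% to 1.42% in the other 3 myeloid and 1.33% to 2.07% in the 4 lymphoid libraries. A wrong label and a mixed sample were not separated, and no biological explanation was tested.

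The other libraries far from their group are given as values. The total was 46 counts in naive 1 µM myeloid replicate 2 (others 5395 to 5827) and 49225 in TNBS 20 µM myeloid replicate 1 (others 4901 to 10837). Myeloid-high transcripts took 3.14% of counts in naive 20 µM myeloid replicate 2 (others 1.43% to 1.65%). Lymphoid-high transcripts took 1.27% in naive 20 µM myeloid replicate 1 (others 0.812% to 0.883%) and 2.07% in TNBS 1 µM lymphoid replicate 4 (others 1.33% to 1.44%). ENSDART00000194692 took 0.474% in naive 20 µM myeloid replicate 2 (others 0 to 0.0521%), ENSDART00000194405 took 0.00852% in TNBS control lymphoid replicate 4, which is 1 count (others 0), and ENSDART00000187593 took 0.191% in TNBS 20 µM myeloid replicate 2 (others 0.0396% to 0.04996%). ENSDART00000037346 took 0.186% in TNBS control myeloid replicate 4 (others 0.396% to 0.427%).

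Differences between effects were called in 2 comparisons. The TNBS effect differed between cell classes for 2 transcripts, and 13 of 100 splits of the libraries gave as many, the highest other giving 7. The effect of 20 µM propyzamide differed between naive and TNBS myeloid libraries for 1 transcript, and 7 of 100 splits gave as many, the highest other giving 3. Chance could be excluded in neither case.

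Splits of the same libraries were counted for the other comparisons too. For lymphoid against myeloid, 1 of 100 splits, the real one, reached 37 calls and the highest other gave 5. For TNBS against naive averaged over doses in myeloid libraries, 1 of 100 reached 7 and the highest other gave 1. In both, 1 of 100 is the smallest share these splits can give, and it was not adjusted for the comparisons split. The splits alone therefore do not exclude chance. The average over doses was also chosen after the data were seen, and its count fell as low as 2 without 1 library. In naive lymphoid libraries 31 of 35 splits gave at least the 2 calls at 20 µM and 30 of 35 at least the 1 call at 1 µM, with up to 5 calls each, so chance cannot be excluded there. Naive control replicate 1 falls in 1 of the compared groups in every split. These counts may thus largely reflect that library, without which both comparisons had 0 calls. Where 0 transcripts were called, every split gives at least as many by definition, so this comparison of counts says nothing about chance there. The highest other split gave 6 calls for TNBS against naive in lymphoid controls and 0 to 4 in the other comparisons.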

How the results depend on the processing

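The fits with TMM with singleton pairing, without the 2 libraries that stood apart and at equal depth were added after the data were seen. Outside the fits without 1 library, 165 counts of calls stayed within 1.5 times the reported count, 16 were higher and 26 lower. A count of 0 that stayed at 0 is among the 165, and 13 of the 16 propyzamide comparisons had 0 calls. The 165 therefore do not measure how stable the called transcripts were. Size factors and the length offset moved no count by more than 1. For 20 µM in naive lymphoid libraries the 2 calls became 0 with DESeq2, with low-depth libraries left out, without the 2 libraries apart and with the compared groups alone, and 20 others with no filter. Voom called 2 others and turned the direction of ENSDART00000117596 (0.59) and ENSDART00000126982 (0.57). Without the 2 libraries apart these stood at 1.06 and 0.35. At 1 µM the 1 call became 0 with DESeq2, voom, low-depth libraries left out, the 2 libraries apart left out and the compared groups alone, and 9 others with no filter, and ENSDART00000126982 stood at 0.38 with voom and 0.01 (0.0068) without the 2 libraries. TNBS against naive in myeloid libraries gave 3 with no filter, low-depth libraries left out or the index block, 2 with voom, 18 with the compared groups alone and 11 at equal depth (8 higher, 3 lower, of 36 tested). The difference of the TNBS effect between cell classes gave 0 with no filter, voom, low-depth libraries left out, the 2 libraries apart left out, the compared groups alone and the index block. The myeloid interaction gave 0 with DESeq2, no filter, voom, singleton pairing, low-depth libraries left out and the index block. Comparisons with 0 calls gained some: 3 with DESeq2 for 1 µM and for 20 µM against 1 µM in naive myeloid libraries (1 for the latter with low-depth libraries left out), 5 with no filter for 20 µM averaged in lymphoid libraries, 1 with DESeq2 and 1 with the compared groups alone for 20 µM averaged in myeloid libraries, 1 with voom for the lymphoid interaction, 1 without the 2 libraries apart and 1 with the compared groups alone for 20 µM against 1 µM in naive lymphoid libraries, and 1 with the compared groups alone for 1 µM in TNBS myeloid libraries.

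Leaving out 1 library at a time gave 33 to 44 calls between cell classes, 0 to 5 for the difference of TNBS effects, 0 to 2 and 2 to 8 for TNBS against naive in lymphoid and myeloid controls, 0 to 5 and 0 to 2 for 20 µM and 1 µM in naive lymphoid libraries, 0 to 1 for both interactions and for 1 µM in naive myeloid libraries, 0 to 2 for 20 µM against 1 µM in naive myeloid libraries, and 0 in the other 10 planned comparisons. For TNBS against naive averaged over doses it gave 0 to 1 in lymphoid and 2 to 13 in myeloid libraries. Without naive control lymphoid replicate 1, ENSDART00000117596 stood at 1.06 and ENSDART00000126982 at 0.35 for 20 µM, the former reaching -4.93 and the latter -3.75 without other libraries. For 1 µM ENSDART00000126982 ranged from -4.04 to 0.01. The gene list and marker unit alternatives were not run, since no names were attached. Depth limited the tests to 116 of 59290 listed transcripts in myeloid and 203 in lymphoid libraries.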

Other observations

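Fold changes at 20 µM and 1 µM against the same controls were compared across transcripts, which are not independent replicates. This comparison was chosen after the data were seen. In TNBS myeloid libraries Pearson's r was 0.721 and Spearman's rho 0.725 over 116 transcripts, and 20 simulations of unchanged groups against the shared controls gave r between 0.293 and 0.541. The covariance was 0.416 against a simulated mean of 0.192, and with the controls split into separate pairs r was 0.484 on average (0.469 to 0.504 over 3 splits). Leaving out 1 of the 12 libraries moved r between 0.503 and 0.771. In naive lymphoid libraries r was 0.652 against simulated values of 0.364 to 0.608, but with split controls it was 0.0543 on average. The corresponding r with split controls was -0.00914 in TNBS lymphoid and 0.0114 in naive myeloid libraries, where r with shared controls was 0.595 (simulated 0.379 to 0.555) and 0.192 (simulated 0.260 to 0.617). Leaving out 1 library moved r with shared controls between 0.494 and 0.784 in naive lymphoid libraries. It moved between 0.342 and 0.753 in TNBS lymphoid and between 0.0981 and 0.477 in naive myeloid libraries. No transcript passed the test at either dose in TNBS myeloid libraries. The TNBS controls of that set were deeper than the 1 µM libraries (mean log10 total 4.46 against 3.92, exact permutation test p = 0.0286, n = 4 each, adjusted p = 0.286 over 30 tests).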
